A study of Homo sapiens with 6 samples.

How the data were processed

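RNA was measured in 6 libraries of human cells, 2 of undifferentiated IMR90.4 induced pluripotent stem cells at day 0 and 4 of day 35 organoids that carried a SIX6 reporter, 2 GFP-negative and 2 GFP-positive. The series text speaks of 7 samples, and the 7th is not analysed here. Per the labels, the stem cells were kept under hypoxia, retina cups were pooled by 10 to 12, total RNA with an RNA integrity number above 8 was used, and libraries were made with a Nextera kit, whose reads do not mark the strand. The authors' processing notes name TopHat2 2.0.12 and DESeq2, while the genome build, annotation and counting tool are not given in the sources used here.

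The authors provided a deposited table of normalized counts, a signal unit in which whole read counts had been divided by 1 size factor per library. It holds 39894 Ensembl gene identifiers and 6 columns. The value of 1 read was fitted in each column from its smallest values, starting from the lowest value above 0, whole reads were recovered by division, and 100% of values up to 1000 reads then lay within 0.1 of a whole number in each library. Recovered totals ranged from 1459875 to 5076514 reads. The size factors equalled those of the median-of-ratios method on the 6 libraries, so recomputing them moved nothing. A gene identifier without a symbol held 20.5% and 20.2% of reads at day 0, 11.9% and 18.6% in GFP-negative and 13.1% and 9.48% in GFP-positive pools. Symbols were assigned to 37155 identifiers from a reference annotation and 2739 had none. Reads shared with paralogs or pseudogenes (HSPA1A and HSPA1B, POU5F1, NANOG, LDHA, PGK1, ENO1, KRT8, KRT18 and the mitochondrial genes) cannot be told apart in gene counts. Without strand marking this also holds for the 61 of 162 named genes whose exons overlap those of another gene in GENCODE v29, among them PAX6, PMEL, CYP1B1 and HOXB5.

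Genes with a mean of at least 10 normalized counts over the 6 libraries were tested, 15553 in all, after log2 transformation with a pseudocount of 1. All 6 libraries entered 1 limma fit with 3 groups, empirical Bayes moderation with an intensity trend, and two-sided tests for GFP-positive against GFP-negative pools and for each against day 0. A gene counted as changed at a Benjamini-Hochberg adjusted p under 0.05. Replicate letters entered no test except as an alternative, since the labels do not say that equal letters share a culture. Genes that changed in opposite directions from day 0 also had to differ between the day 35 groups. R 4.3.3 was used with limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0, and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

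The samples, contrasts, tests, 36 gene lists, the rule for named genes and all alternatives except 4 were chosen before the data were examined. The lists held 541 genes, of which 527 were matched. Each list was tested with camera, which compares a list with all other genes, at a preset inter-gene correlation of 0.01 and again with an estimated correlation, and with fry as a description. Of 35 lists with a tested member, camera called 21 in GFP-positive against GFP-negative pools, 18 in GFP-positive pools against day 0 and 19 in GFP-negative pools against day 0, and 0 with an estimated correlation in each. The lens list had no tested member. Named genes were SIX6, members of the lists, and, outside the lists, the 10 genes with the largest differences per direction between the day 35 groups, the 6 per direction against day 0, and the 5 per direction among those with opposite changes. These had to pass the threshold, and all but the last group needed a mean of at least 50 and no overlap between groups. Unnamed clones and pseudogenes were passed over.

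A fold against a group without reads is given as a bound against a floor of 3 reads over the group, which is 1.065 normalized counts at day 0. The level set against the floor is the reads of the other group over its summed size factors, which can differ from the mean of its 2 libraries. With 1 to 3 reads in a group the ratio of read rates is given with an exact 95% counting interval. Alternatives were pseudocounts of 0.25 and 5, no filter and a minimum mean of 50, TMM factors, recomputed size factors, quantile normalization, a fit of the 2 compared groups alone, limma without trend, edgeR quasi-likelihood and DESeq2 on the recovered reads, a log2 fold change of at least 1, each library left out in turn, and a replicate block for GFP-positive pools against day 0. Protein-coding genes alone, subtraction of a background estimated from exon length and olfactory receptor genes, the same with the silent family of the largest rise between the day 35 groups (PRAME and SPANX testis genes), and the eye field list without SIX6 were added after the values were seen. Where 1 library of a group was left out, the remaining one was assumed to vary like the other groups.

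The procedure was tested on simulated data with 100 genes changed 2-fold and 100 changed 4-fold per contrast, up and down in equal numbers. For GFP-positive against GFP-negative pools limma recovered 41% and 89% of them and called 5 unchanged genes of 15315 tested. For GFP-positive and GFP-negative pools against day 0 it recovered 53% and 48% at 2-fold and 90% and 91% at 4-fold. A planted list of 15 genes raised 2-fold was called by camera with the preset correlation in all 3 contrasts, with 0 of 50 random lists called, and in none with an estimated correlation. Genes were simulated independently, so this does not cover lists whose members vary together, such as cell cycle genes (estimated correlation 0.857). Each simulated gene also had the same dispersion in all 3 groups. The real groups differed, with a chi-square per gene of 7.89 within GFP-negative pools against 2.20 at day 0 and 3.20 within GFP-positive pools. The simulation therefore does not measure false calls under unequal spread. With an estimated correlation the planted list had camera Benjamini-Hochberg adjusted p from 0.101 to 0.153, so a list that fails there is not shown to be unshifted.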

Results

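RNA was sequenced from human retinal organoids grown from IMR90.4, an established induced pluripotent stem cell line, that carried a green fluorescent protein (GFP) reporter for SIX6, a homeobox transcription factor of the eye field and neural retina. Day 35 retina cups had been pooled, 10 to 12 cups to a pool, and separated into GFP-positive and GFP-negative material. Undifferentiated stem cells at day 0 served as the reference. The 6 libraries analysed here formed 3 groups of 2, namely day 0 stem cells (replicates A and B), day 35 GFP-negative pools (replicates a and c) and day 35 GFP-positive pools (replicates a and b). The number of whole reads assigned to genes was 5076514 and 3707485 at day 0, 1459875 and 2499692 in the GFP-negative pools, and 1955522 and 1485855 in the GFP-positive pools. Values below are normalized counts as mean ± SD with n = 2 per group, and log2 fold changes ± SE on the log2(normalized count + 1) scale. Nothing in the descriptions says that the replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. Correlations of log2 values over the tested genes were 0.978 between the day 0 replicates, 0.935 between the GFP-negative and 0.956 between the GFP-positive replicates, and 0.868 to 0.895 between libraries of the 2 day 35 groups. The chi-square per gene between 2 libraries, which grows with read depth, was 2.20 at day 0, 3.20 within the GFP-positive and 7.89 within the GFP-negative group. GFP-negative replicate a gave 8.02 and 7.45 against the GFP-positive libraries, so by this measure it lay about as far from its own replicate as from the other group, and replicate c gave 15.8 and 19.2. Reads over olfactory receptor genes, a family taken as silent in these cells, averaged 0.178 normalized counts per kb of exon at day 0, 0.462 in GFP-negative and 0.675 in GFP-positive pools, a GFP-positive to GFP-negative ratio of 1.46. All intervals and floors given here cover counting error only.

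SIX6 itself was read first, because the reporter defines the groups. Its normalized count was 185 and 118 in the GFP-positive pools, 1.45 and 0 in the GFP-negative pools and 0.615 and 0.839 at day 0. These levels rest on 266 reads in the GFP-positive group, 1 read in the GFP-negative group and 2 reads at day 0. The ratio of GFP-positive to GFP-negative read rates was 268 (95% counting interval 47.7 to 10638), and of GFP-positive to day 0 read rates 219 (95% counting interval 60.0 to 1816). Both GFP-positive libraries lay above both GFP-negative libraries, and the difference passed the test (limma, Benjamini-Hochberg adjusted p = 1.74e-05).

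The comparison of GFP-positive with GFP-negative pools asks which genes set reporter-positive material of the cups apart from reporter-negative material. GFP-positive pools held more RNA of 8 of 13 measured pigment epithelium genes and of 8 of 15 measured neural retina progenitor genes. CYP1B1, a cytochrome P450 enzyme expressed in the developing eye, reached 4528 ± 721 against 17.1 ± 10.6, a 273-fold difference (log2 8.09 ± 0.31). DCT, a melanin synthesis enzyme, stood at 2724 ± 274 against 38.1 ± 19.8, and ALDH1A3, a retinoic acid synthesizing enzyme, at 416 ± 59.6 against 3.14 ± 1.71. GFP-negative pools held more RNA of all 15 measured HOX genes and of 14 of 17 pan-neuronal genes. Genes higher there included HOXB5 (400.1 ± 68.3 against 36.7 ± 13.5), the proneural factor NEUROG2 (214 ± 67.8 against 7.35 ± 2.92) and the neuronal protein gene STMN2 (819.7 ± 71.0 against 47.2 ± 13.5). Of 15553 genes tested, 1450 differed (limma, Benjamini-Hochberg false discovery rate of 5%), of which 488 were higher and 962 lower in GFP-positive pools.

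Eye field genes were mostly higher. Of the 8 measured eye field transcription factors, 5 were higher and 2 lower in GFP-positive pools, the same counts as adjusted over the list alone. Besides SIX6, LHX2 was 15.8-fold higher (392 ± 44.5 against 24.4 ± 7.83), RAX 13.0-fold and SIX3 4.05-fold. EYA1 was higher by 1.81 ± 0.51 on the log2 scale, and by 0.00 once the background of the silent family with the largest rise was subtracted. PAX6 and OTX2, which are also expressed in the neural tube outside the eye, went the other way, PAX6 by -1.01 ± 0.29 (limma, Benjamini-Hochberg adjusted p = 0.0464) and OTX2 by -1.88 ± 0.20 on the log2 scale. NR2E1 did not differ beyond the replicate spread (105 ± 31.4 against 123 ± 71.6). As a set these genes ranked higher than other genes (camera, Benjamini-Hochberg adjusted p = 0.00494, and adjusted p = 0.211 with an estimated correlation). SIX6 is higher there by the choice of the groups, and in a test added after the values were seen, without it, 4 of 7 members were higher, 2 lower and the median 1.81 (camera, Benjamini-Hochberg adjusted p = 0.0441, and adjusted p = 0.419 with an estimated correlation).

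Among 15 measured neural retina progenitor genes, 8 were higher and 4 lower, again the same counts as adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.0152, and adjusted p = 0.353 with an estimated correlation). The set test no longer passed without GFP-negative replicate a, at a median log2 fold change of 1.30 in place of 1.34, nor with a minimum mean of 50, at 0.78. HMX1 stood at 107 ± 61.7 against 1.21 ± 0.342. MAB21L1 was 12.6-fold higher, and FGF19 stood at 118 ± 18.7 against 3.13 ± 2.39. Members lower in GFP-positive pools included HES5, HES6 and SLC1A3, with HES5 at 5.64 ± 2.37 against 164 ± 57.5. CCND1 differed by -0.28 ± 0.20 and LIN28B by 0.21 ± 0.19 on the log2 scale, and neither passed the test.

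Pigment epithelium genes were also mostly higher, and DCT is a member of both this list and the neural retina progenitor list. Of 13 measured members, 8 were higher and 1 lower, and 9 were higher as adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 1.46e-06, and adjusted p = 0.11 with an estimated correlation). The melanosome protein gene PMEL was 44.4-fold higher (832 ± 151 against 21.7 ± 18.4), the transcription factor TFEC 31.3-fold, TYR 11.7-fold and MITF 6.34-fold. OTX1 was the member that was lower, at 23.5 ± 2.22 against 156 ± 11.3. BEST1, MLANA, OCA2 and LRAT did not pass the test, with log2 differences between 0.25 ± 0.23 and 0.87 ± 0.35.

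The dorsal and ventral retina patterning list did not shift as a set (camera, Benjamini-Hochberg adjusted p = 0.0971), with 5 of 16 members higher and 3 lower, and 7 higher and 4 lower as adjusted over the list alone. PAX2 and VAX1, genes of the optic stalk and ventral eye, were 18.0-fold and 13.2-fold higher, and ALDH1A1 39.9-fold higher. EPHA3, EFNB2 and EFNB1, which encode guidance receptors and ligands, were lower by 13.5-fold, 2.93-fold and 2.50-fold.

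**Figure D1:**
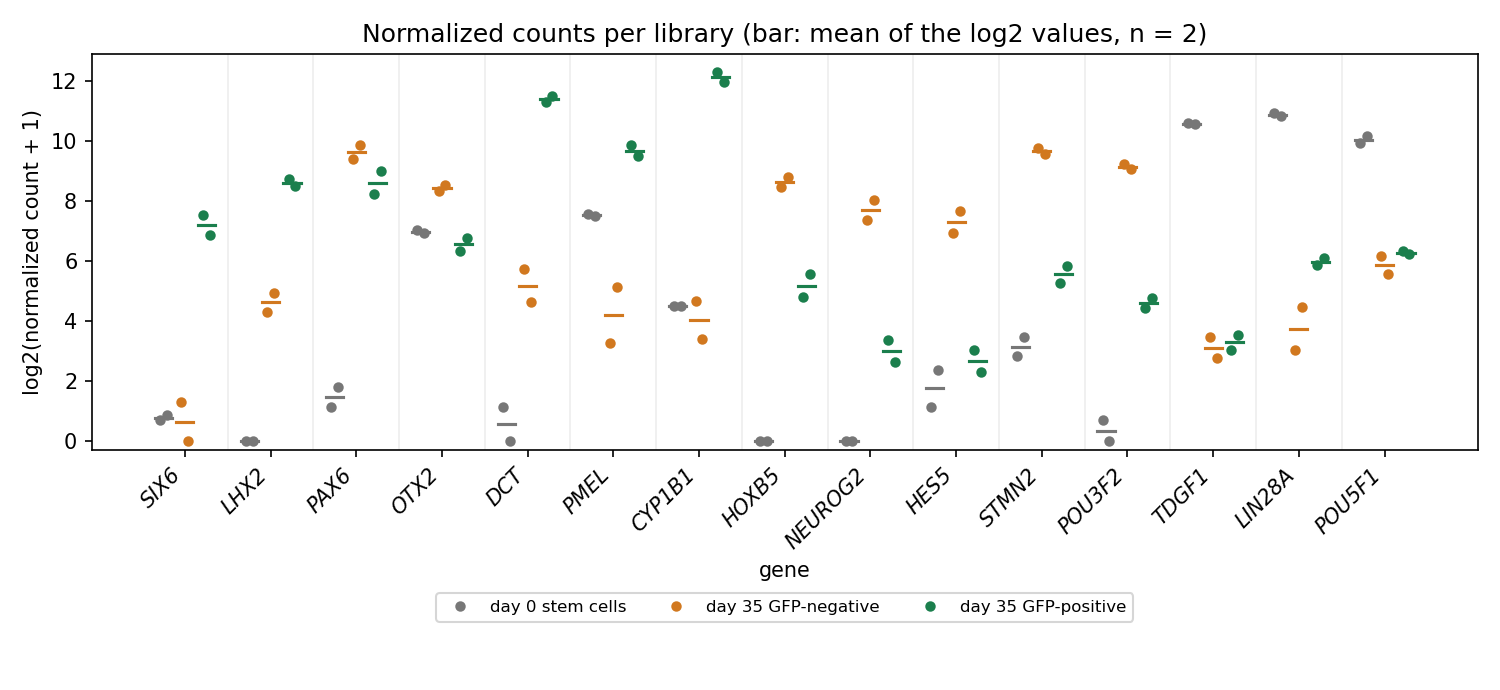
Normalized counts (vertical axis, log2 of normalized count + 1) of 15 genes in each of the 6 libraries, as points, with a bar at the mean of the log2 values of each group of 2. SIX6, LHX2, DCT and PMEL lie highest in the GFP-positive pools, HOXB5, NEUROG2, HES5, STMN2 and POU3F2 lie highest in the GFP-negative pools, and TDGF1, LIN28A and POU5F1 lie highest at day 0.

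HOX and pan-neuronal genes made up the other side. All 15 measured HOX genes were lower in GFP-positive pools, the same count as adjusted over the list alone, with a median log2 fold change of -3.29 (camera, Benjamini-Hochberg adjusted p = 4.43e-19, and adjusted p = 0.11 with an estimated correlation). HOXB9 was 17.5-fold lower, HOXB5 10.9-fold, HOXA5 12.3-fold and HOXB2 8.47-fold. Of 17 pan-neuronal genes, 14 were lower and none higher, likewise as adjusted over the list alone, with a median of -2.62 (camera, Benjamini-Hochberg adjusted p = 2.71e-14, and adjusted p = 0.11 with an estimated correlation). STMN2 was 17.3-fold lower, GAP43 10.7-fold and DCX 7.67-fold (149 ± 10.4 against 1146 ± 95.9), whereas TUBB3, SYP and RBFOX3 did not pass. Among 14 neural progenitor genes 9 were lower, and 10 as adjusted over the list alone. SOX1 was lower by 4.54-fold and NES by 4.25-fold (camera, Benjamini-Hochberg adjusted p = 4.12e-07, and adjusted p = 0.11 with an estimated correlation). VIM and SOX3 in that list differed by -0.16 ± 0.16 and -0.06 ± 0.22 on the log2 scale and did not pass.

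Of the brain region lists, those of the dorsal telencephalon and of the hypothalamus and diencephalon passed as lower. Dorsal telencephalon genes were lower for 7 of 12 members and higher for FEZF2 alone (104 ± 29.2 against 24.6 ± 10.2), with 7 lower and 2 higher as adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.000322, and adjusted p = 0.119 with an estimated correlation). The lower members included NEUROG2, which was 26.0-fold lower, and NEUROG1, which was 7.26-fold lower. Hypothalamus and diencephalon genes were lower for 6 of 9 members, among them SIM1, IRX3, BARHL2 and TCF7L2, and higher for SIX3 and RAX, which the eye field list also holds, and the counts were unchanged as adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.00303, and adjusted p = 0.152 with an estimated correlation). With a minimum mean of 50, which left 3 of these genes, the median turned from -2.68 to 2.02 and the test no longer passed. Of 9 retinal ganglion cell genes 5 were lower, and 6 as adjusted over the list alone, namely EBF1, EBF3, SNCG, NEFM and GAP43 and then POU4F1, while THY1 was 3.60-fold higher (camera, Benjamini-Hochberg adjusted p = 0.000393, and adjusted p = 0.119 with an estimated correlation). NEFM and GAP43 are also in the pan-neuronal list.

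Signalling genes differed by pathway. FGF ligands and targets were higher for 7 of 15 members and lower for 2, and higher for 11 as adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 7.01e-05, and adjusted p = 0.119 with an estimated correlation). The feedback inhibitors SPRY4 and DUSP6 were 6.97-fold and 5.83-fold higher and the target transcription factor ETV5 5.18-fold, while the receptors FGFR2 and FGFR3 were lower by 2.37-fold and 4.40-fold. Against day 0, 2 of the 15 FGF members were higher and 8 lower in GFP-positive pools, at a median of -0.63. That set did not pass (camera, Benjamini-Hochberg adjusted p = 0.111, and adjusted p = 0.295 with an estimated correlation). Notch pathway genes were lower for 8 of 13 members, the same as adjusted over the list alone. Lower members included the ligands DLL3 by 9.87-fold, DLL1 by 8.29-fold and JAG1 by 5.88-fold, while HES1 was 2.56-fold higher (camera, Benjamini-Hochberg adjusted p = 4.17e-05, and adjusted p = 0.119 with an estimated correlation). WNT ligands and R-spondins were lower for 4 of 7 and canonical WNT targets for 4 of 9, or 4 and 5 as adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.00418 and 0.00486, and adjusted p = 0.152 with an estimated correlation for both). WNT4 was 16.3-fold and AXIN2 3.57-fold lower, whereas WNT5A was 2.88-fold higher. The WNT receptor gene FZD5, which is expressed in the eye field, was 18.7-fold higher (344 ± 51.6 against 17.4 ± 0.00944) in a list of antagonists and receptors that did not shift as a set. BMP targets were lower for 5 of 10, and 6 as adjusted over the list alone. MSX2 was lower by 8.61-fold and ID3 by 2.26-fold (camera, Benjamini-Hochberg adjusted p = 0.00639, and adjusted p = 0.19 with an estimated correlation). Retinoic acid genes split 3 higher and 3 lower, or 4 and 5 as adjusted over the list alone. ALDH1A3, ALDH1A1 and STRA6 were higher and DHRS3, RARB and CYP26B1 lower.

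Extracellular matrix and adhesion genes were higher for 9 of 18 members, as also adjusted over the list alone. COL2A1 stood at 691 ± 149 against 97.9 ± 7.45, and LAMC1 and FBN2 were 3.27-fold and 3.32-fold higher, while CDH2 and CDH4 were lower (camera, Benjamini-Hochberg adjusted p = 0.000458, and adjusted p = 0.204 with an estimated correlation). Hypoxia response genes were lower for 10 of 14 members and 12 as adjusted over the list alone. The glycolytic enzyme gene LDHA stood at 433 ± 106 against 1469.8 ± 431 and the mitophagy gene BNIP3 was 3.11-fold lower (camera, Benjamini-Hochberg adjusted p = 3.90e-06, and adjusted p = 0.244 with an estimated correlation). Pluripotency genes were higher for 5 of 15, or 6 as adjusted over the list alone, at levels far under those of day 0 except LEFTY2, and lower for SOX2 and SALL4 (camera, Benjamini-Hochberg adjusted p = 0.00792, and adjusted p = 0.204 with an estimated correlation). The pluripotency set no longer passed without GFP-negative replicate c, at a median of 0.36 in place of 0.53, nor with no filter on low values, at 0.47. LIN28A, an RNA-binding protein gene of stem cells and early progenitors, stood at 62.5 ± 6.96 against 14.2 ± 9.88. Cell cycle genes shifted slightly down as a set with a median of -0.34, and TYMS was the 1 of 19 to pass, with none as adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.0107, and adjusted p = 0.607 with an estimated correlation). That median lay at percentile 12.9 of 10000 random lists matched on size and mean expression, and fry gave a Benjamini-Hochberg adjusted p of 0.311. Without GFP-negative replicate c the median was -0.07 and the set no longer passed. MKI67 stood at 565 ± 49.9 against 734 ± 141 and did not pass the test.

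Mitochondrially encoded genes were lower for 3 of 13, or 4 as adjusted over the list alone. MT-ND4 stood at 2599.5 ± 821 against 4810.0 ± 111 (camera, Benjamini-Hochberg adjusted p = 0.0256, and adjusted p = 0.599 with an estimated correlation). The set median of -0.33 lay at percentile 38.7 of matched random lists, and fry gave a Benjamini-Hochberg adjusted p of 0.209. The mitochondrial set no longer passed without GFP-negative replicate a (median -0.29) without GFP-positive replicate a (median -0.12), or with protein-coding genes alone (median -0.33). Surface ectoderm and epithelial genes were higher for 2 of 11, or 4 higher and 1 lower as adjusted over the list alone. The keratin gene KRT8 was 2.38-fold higher (camera, Benjamini-Hochberg adjusted p = 0.0444, and adjusted p = 0.211 with an estimated correlation). This set no longer passed without GFP-negative replicate c (median 0.23) or GFP-positive replicate b (median 0.78). Mesenchyme and fibroblast genes were higher for 2 of 10, or 3 as adjusted over the list alone. The collagen gene COL1A2 and the smooth muscle actin gene ACTA2 stood at 192 ± 35.4 against 95.5 ± 8.24 and 79.4 ± 7.27 against 42.0 ± 6.16 (camera, Benjamini-Hochberg adjusted p = 0.00762, and adjusted p = 0.211 with an estimated correlation).

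**Figure D2:**
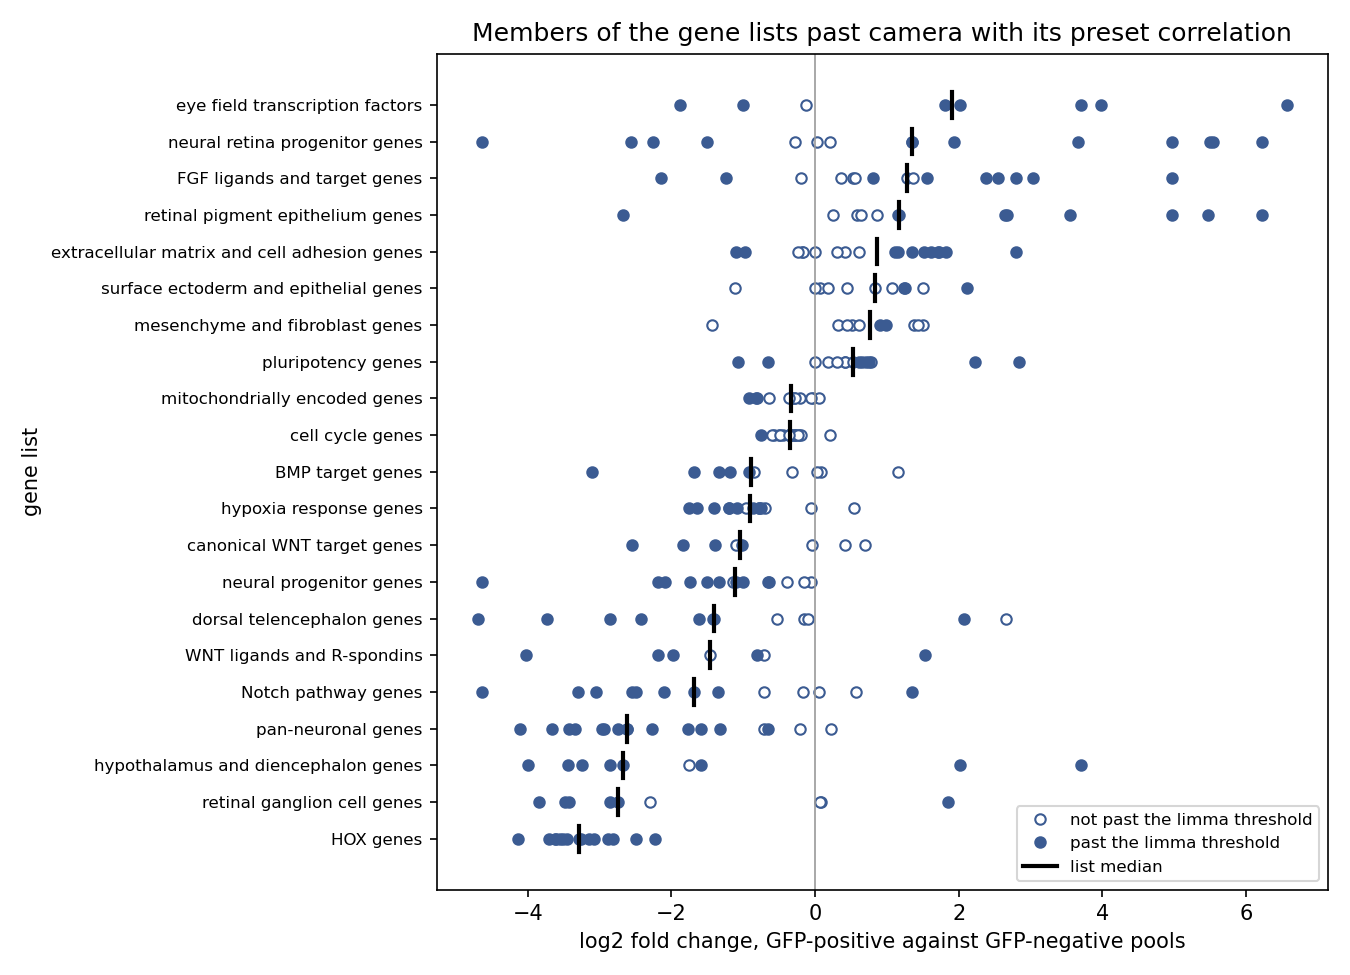
Log2 fold change of GFP-positive against GFP-negative pools (horizontal axis) for the measured members of 21 gene lists whose set shift passed camera with its preset correlation, 1 point per gene, with a vertical bar at the list median and filled points for genes past the limma threshold. The HOX genes all lie below 0, with a median of -3.29, and the eye field list has a median of 1.91.

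Outside the fixed lists, among genes with a mean of at least 50 over the 6 libraries and no overlap between the groups, those with the largest differences in favour of GFP-positive pools after CYP1B1 were CXCL12, ADAMTS16, PKDCC, RGS5, FLRT2, LINC01833, SHISA2, MAN1A1 and RBMS1, from 26.6-fold for the chemokine gene CXCL12 down to 8.23-fold for RBMS1. CXCL12 stood at 229.7 ± 17.1 against 7.72 ± 1.37, and FLRT2 at 439.6 ± 121 against 28.2 ± 3.08. The largest in favour of GFP-negative pools were EDIL3, POU3F2, SYT4, NHLH2, SCUBE2, BRINP1, TAGLN3, RGS16, POU3F3 and SKAP2, from 23.5-fold to 8.35-fold. POU3F2, a neuronal POU-domain factor, stood at 23.7 ± 3.89 against 571 ± 46.4, and SYT4, a synaptotagmin gene of neurons, at 15.1 ± 0.818 against 265 ± 12.1.

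No set call between the day 35 groups held with an estimated correlation, and several also ended under other alternatives. With a minimum mean of 50 those of BMP targets (median -0.86), Notch genes (-1.35), WNT ligands (-0.72), ganglion cell genes (-1.34), surface ectoderm genes (0.18) and mitochondrial genes (-0.33) ended. With quantile normalization those of cell cycle (-0.19), mitochondrial (-0.21) and surface ectoderm genes (0.85) ended, and with no filter those of mesenchyme (0.51) and surface ectoderm genes (0.44). Subtraction of the largest background ended those of BMP targets (-1.06), cell cycle (-0.40), mitochondrial (-0.33) and surface ectoderm genes (0.54), which had stood at -0.89, -0.34, -0.33 and 0.84. It also ended calls of single genes whose log2 differences were larger than without it or nearly the same, namely PAX6 (-1.19 in place of -1.01), KRT8 (1.41 in place of 1.25), LIN28A (3.35 in place of 2.23), SIM1 (-3.95 in place of -2.68), TYMS (-0.82 in place of -0.75), WNT5A (1.85 in place of 1.53), CRB1 (1.71 in place of 1.44), ACTA2 (0.93 in place of 0.91) and MT-ND4 (-0.93 in place of -0.92), while the difference of SPRY4 shrank from 2.80 to 2.15. Subtraction of the olfactory background ended those of mitochondrial (-0.33) and surface ectoderm genes (0.88).

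The total of 1450 fell to 484 without GFP-positive replicate a and to 534 without GFP-positive replicate b, rose to 3295 without GFP-negative replicate a, and was 903 with DESeq2 on the recovered reads, 630 in limma without a mean-variance trend and 494 with no filter on low values. The split of 488 higher and 962 lower became 757 and 931 with quantile normalization and 815 and 946 in edgeR on the recovered reads, and 260 and 1562 after subtraction of the largest background. With the 2 compared groups fitted alone the total was 1119, with 377 higher and 742 lower.

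The comparison of GFP-positive pools with day 0 stem cells sets reporter-positive day 35 material against undifferentiated cells. Most measured eye field and retina patterning genes rose. LHX2, with no read at day 0, was at least 372-fold higher relative to a floor of 3 reads over the day 0 group (bounds compare reads summed over each group and divided by its summed size factors, not the printed means), and PAX2 and VAX1 were at least 196-fold and 130.5-fold higher. Pluripotency genes fell. TDGF1 went from 1544 ± 21.5 to 8.95 ± 2.30, DNMT3B from 2478 ± 113 to 42.2 ± 5.45 and POU5F1 from 1070.5 ± 134 to 77.4 ± 2.96. In all, 10112 of 15553 genes changed (limma, Benjamini-Hochberg false discovery rate of 5%), 4563 up and 5549 down.

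Of the eye field factors 7 of 8 rose, as also adjusted over the list alone, while EYA1 turned to -1.01 after subtraction of the largest background, and OTX2 did not pass (94.6 ± 21.3 against 126 ± 7.17). PAX6 went from 1.87 ± 0.911 to 409 ± 152, and the camera test gave a Benjamini-Hochberg adjusted p of 0.000116, against adjusted p = 0.182 with an estimated correlation. Pigment epithelium genes rose for 12 of 13 members and retina patterning genes for 15 of 16, with identical counts as adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 9.04e-05 and 2.72e-07, and adjusted p = 0.173 with an estimated correlation for both). MITF went from 1.54 ± 2.17 to 147 ± 10.4, ALDH1A1 from 4.87 ± 0.946 to 214 ± 93.0 and NR2F1, a nuclear receptor gene with no read at day 0, to 894 ± 48.8, at least 836-fold higher. LRAT was the pigment epithelium member that fell, from 270.5 ± 15.8 to 39.6 ± 1.75. HOX genes also rose, for 14 of 15 members and as many adjusted over the list alone, to levels such as 36.7 ± 13.5 for HOXB5 (camera, Benjamini-Hochberg adjusted p = 1.03e-07, and adjusted p = 0.182 with an estimated correlation). The HOX median was 3.29 on the log2 scale, and 3.04 with members lacking a day 0 read set at their bound. All 15 measured HOX genes lay lower here than in GFP-negative pools, at a median of -3.29. Reads over PRAME and SPANX genes rose from 0.242 at day 0 to 2.85 normalized counts per kb in GFP-positive pools. Subtraction of that background ended the rise calls of HOXB9 (0.34), NEUROG2 (1.02), IRX3 (0.00) and BARHL2 (0.00). Of 138 calls of named genes against day 0, 14 were lost and 6 changed direction.

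Pan-neuronal genes rose for 11 of 17, or 12 as adjusted over the list alone. MAP2 went from 25.4 ± 5.01 to 409 ± 12.8, while NEFM fell (camera, Benjamini-Hochberg adjusted p = 7.13e-05, and adjusted p = 0.173 with an estimated correlation). Of 15 pluripotency genes 14 fell and LEFTY2 rose, the same as adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 3.91e-06, and adjusted p = 0.173 with an estimated correlation). Epithelial genes fell for 10 of 11, with identical counts as adjusted over the list alone. Members that fell included CLDN6 (925 ± 34.2 to 7.46 ± 8.68) and EPCAM (688 ± 3.49 to 7.90 ± 3.78), while KRT15 rose (camera, Benjamini-Hochberg adjusted p = 0.000691, and adjusted p = 0.182 with an estimated correlation). Hypoxia response genes, read against stem cells that had been kept under low oxygen, fell for 11 of 14, the same as adjusted over the list alone. LDHA went from 4010.0 ± 50.9 to 433 ± 106 and ENO1 from 6348 ± 457 to 1387 ± 18.4 (camera, Benjamini-Hochberg adjusted p = 0.00337, and adjusted p = 0.352 with an estimated correlation). Cell cycle genes fell for 16 of 19, as also adjusted over the list alone, such as MCM3 by 5.55-fold, while TOP2A did not pass (camera, Benjamini-Hochberg adjusted p = 0.00561, and adjusted p = 0.548 with an estimated correlation).

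Further sets rose, each with the same counts as adjusted over the list alone, namely neural retina progenitor genes (10 of 15 up and 2 down), retinoic acid genes (11 of 13 up), dorsal telencephalon genes (7 of 12 up), hypothalamus and diencephalon genes (6 of 9 up), WNT ligands (6 of 7 up), neural progenitor genes (7 of 14 up and 4 down) and canonical WNT targets (4 of 9 up). Their camera tests gave Benjamini-Hochberg adjusted p from 0.000144 for retinoic acid genes to 0.0456 for WNT targets, and adjusted p from 0.182 to 0.246 with an estimated correlation. The WNT target call did not hold without GFP-negative replicate a or c, with a pseudocount of 0.25, quantile normalization, the 2 groups alone or either background subtraction, at medians from -0.70 to 0.68. The neural progenitor call did not hold without GFP-negative replicate a or c, with no filter or with the 2 groups alone, each at a median of 1.44. The hypothalamus and diencephalon call ended with a minimum mean of 50, where the median of the members left was 6.20 in place of 2.07, and after subtraction of the largest background, where it was 0.00. The dorsal telencephalon call ended under the same alternatives, with medians of 1.57 and 0.46 in place of 2.16, and the WNT ligand call with quantile normalization (1.39) and that subtraction (0.56), in place of 1.77. Subtraction of the largest background also ended the calls of cell cycle (median -1.22 in place of -1.12), stress response (-3.24 in place of -1.36) and mitochondrial genes (-1.20 in both), quantile normalization those of cell cycle (-0.53) and hypothalamus and diencephalon genes (0.63), and a minimum mean of 50 that of stress response genes (-1.71). FEZF2, a forebrain transcription factor gene, reached 104 ± 29.2 from 1 read at day 0, CRABP1, a retinoic acid binding protein gene, went from 164 ± 17.0 to 709 ± 123, and the frizzled-related protein gene SFRP2 from 1285 ± 77.6 to 2122 ± 346. Mitochondrially encoded genes fell for 11 of 13 and stress response genes for 8 of 11, with the same counts as adjusted over the list alone. FOS went from 136 ± 22.0 to 9.61 ± 3.23 (camera, Benjamini-Hochberg adjusted p = 0.00519 and 0.0145, and adjusted p = 0.43 and 0.19 with an estimated correlation).

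Outside the lists and by the same conditions, the largest rises were in MMRN1, DLK1, LINC01833, CYP1B1, CRB1 and FLRT3. MMRN1 had no read at day 0 and reached 692 ± 28.2, at least 652-fold higher, and CRB1, an apical polarity gene of the retina, reached 184 ± 39.9, at least 176-fold higher. CYP1B1 rose 198-fold and the adhesion protein gene FLRT3 181-fold. The largest falls were in AP1M2, ZSCAN10, VRTN, LARGE2, SPINT1 and RAB17. The stem cell transcription factor gene ZSCAN10 went from 494 ± 32.9 to 3.41 ± 1.09 and SPINT1 from 293 ± 14.2 to 3.03 ± 1.32. The total of 10112 became 5885 with a minimum mean of 50, which tested fewer genes, and 11267 with the replicate letter as a block, letters that share no stated origin between the groups. Quantile normalization moved the median log2 fold change of all genes by 0.18 here and by 0.12 for GFP-negative pools against day 0.

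The comparison of GFP-negative pools with day 0 stem cells sets reporter-negative day 35 material against undifferentiated cells. HOX and pan-neuronal genes rose and pluripotency genes fell. POU3F2 went from 0.307 ± 0.435 to 571 ± 46.4, the microtubule-binding protein gene DCX from 13.5 ± 0.0716 to 1146 ± 95.9, and HOXB5, with no read at day 0, to 400.1 ± 68.3, at least 385-fold higher. TDGF1 fell to 7.96 ± 3.07 and LIN28A from 1892 ± 90.7 to 14.2 ± 9.88. Of 15553 genes, 8315 changed (limma, Benjamini-Hochberg false discovery rate of 5%), 3610 up and 4705 down.

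All 15 measured HOX genes and 15 of 17 pan-neuronal genes rose, as many as adjusted over the list alone. Their medians were 6.91 and 5.26 on the log2 scale, and 6.80 for the HOX genes with members lacking a day 0 read at their bound (camera, Benjamini-Hochberg adjusted p = 3.71e-13 and 1.78e-10, and adjusted p = 0.101 and 0.101 with an estimated correlation). STMN2 rose 92.1-fold, MAP2 47.4-fold, NCAM1 40.1-fold and HOXB7 25.7-fold. Dorsal telencephalon genes rose for 11 of 12, or 12 as adjusted over the list alone. NEUROG2 was at least 210.4-fold higher, and hypothalamus and diencephalon genes rose for 9 of 9, as also adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 1.56e-06 and 1.33e-05, and adjusted p = 0.101 with an estimated correlation for both). Of the named hypothalamus and diencephalon members, OTP (3.08), SIM1 (3.02) and RAX (1.41) lost the call after subtraction of the largest background. Neural progenitor genes rose for 10 of 14, the same as adjusted over the list alone. ZIC1 was at least 398-fold higher, CDH2 8.30-fold and VIM 19.5-fold higher, while PROM1 and ZIC2 fell (camera, Benjamini-Hochberg adjusted p = 2.94e-05, and adjusted p = 0.101 with an estimated correlation).

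Eye field genes rose here as well, for 6 of 8 members, as also adjusted over the list alone. PAX6 reached 806 ± 183 and SIX3 73.3 ± 6.86, while SIX6 and EYA1 did not pass (camera, Benjamini-Hochberg adjusted p = 0.000284, and adjusted p = 0.144 with an estimated correlation). Subtraction of the largest background ended the call of RAX, at a log2 fold change of 1.41, and turned EYA1 to -1.01. WNT ligands and R-spondins rose for 7 of 7 and canonical WNT targets for 7 of 9, with the same counts as adjusted over the list alone. LEF1 reached 121 ± 8.93 and AXIN2 rose 4.28-fold (camera, Benjamini-Hochberg adjusted p = 0.000149 and 0.000461, and adjusted p = 0.101 with an estimated correlation for both). FGF ligands and targets fell for 11 of 15, or 12 as adjusted over the list alone. SPRY4 went from 380.0 ± 36.6 to 2.41 ± 0.683 and DUSP6 from 840.1 ± 16.6 to 24.6 ± 2.03 (camera, Benjamini-Hochberg adjusted p = 0.00168, and adjusted p = 0.131 with an estimated correlation). Pluripotency genes fell for 13 of 15 and epithelial genes for 10 of 11, as also adjusted over the list alone. SOX2 did not pass the test (463 ± 33.0 against 391 ± 1.44) (camera, Benjamini-Hochberg adjusted p = 2.87e-08 and 1.81e-05, and adjusted p = 0.101 with an estimated correlation for both).

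Retina patterning genes rose for 12 of 16, retinoic acid genes for 9 of 13, BMP targets for 6 of 10, pigment epithelium genes for 9 of 13, neural retina progenitor genes for 8 of 15 and midbrain and hindbrain genes for 4 of 6, with the same counts as adjusted over the list alone. Their camera tests gave Benjamini-Hochberg adjusted p from 9.23e-06 for retina patterning genes to 0.0214 for the last 3 lists, and adjusted p from 0.101 to 0.301 with an estimated correlation. In these lists 3 neural retina progenitor, 2 pigment epithelium and 1 retinoic acid genes fell. The pigment epithelium call did not hold in edgeR (median 2.46), DESeq2 (2.48), the 2 groups alone (1.83), with quantile normalization (0.72), a minimum mean of 50 (1.81) or the largest background subtracted (0.46). The midbrain and hindbrain call did not hold in edgeR (2.02), DESeq2 (2.15), with quantile normalization (1.22), a minimum mean of 50 (1.58) or the largest background subtracted (0.24). CYP26B1, a retinoic acid degrading enzyme gene, reached 222 ± 41.7 and PAX3, a dorsal neural tube factor gene, 85.6 ± 8.48. Stress response genes fell for 8 of 11 and mitochondrially encoded genes for 8 of 13, or 8 and 9 as adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.00692 and 0.0214, and adjusted p = 0.144 and 0.513 with an estimated correlation). Without GFP-negative replicate c the neural retina set (median 1.29) and the mitochondrial set (median -0.75) no longer passed, nor did they with quantile normalization (1.22 and -0.21), and the mitochondrial set also ended with a minimum mean of 50 and after subtraction of the largest background.

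Outside the lists and by the same conditions, POU3F2, TSHZ1, MMRN1, MEIS2, LINC02381 and ZEB1 rose most. The zinc finger gene TSHZ1 reached 502 ± 15.8, the homeobox gene MEIS2 409.8 ± 65.4 and MMRN1 255 ± 30.5, the last at least 235-fold higher, and ZEB1, a repressor of epithelial genes, rose 209-fold. ZSCAN10, AP1M2, VRTN, SPINT1, CYP2S1 and SLC7A8 fell most. CYP2S1 went from 395 ± 15.8 to 1.69 ± 0.34 and SLC7A8 from 641 ± 24.4 to 4.58 ± 4.43. Without day 0 replicate A, the rise was called for 2333 genes in place of 3610, and a minimum mean of 50 gave a total of 5219 in place of 8315.

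Both day 35 groups were compared with the same stem cells, and 50 genes changed in opposite directions from day 0 and also differed between the day 35 groups. Of these, 16 rose in GFP-positive and fell in GFP-negative pools. PMEL went from 187 ± 6.46 at day 0 to 832 ± 151 in GFP-positive and 21.7 ± 18.4 in GFP-negative pools, FGF19 from 33.3 ± 0.772 to 118 ± 18.7 and 3.13 ± 2.39, and CXCL12 from 85.9 ± 0.348 to 229.7 ± 17.1 and 7.72 ± 1.37. The other 34 fell in GFP-positive and rose in GFP-negative pools. The Notch ligand gene DLL3 went from 32.2 ± 0.496 to 9.99 ± 0.817 and 108 ± 8.81, and the ubiquitin ligase adaptor gene KLHL13 from 87.2 ± 17.6 to 36.9 ± 1.94 and 271 ± 9.70. Subtraction of the largest background ended the call of the PMEL rise from day 0, at a log2 fold change of 2.13 in place of 2.14 ± 0.41. The count of 50 became 95 with that subtraction, 18 at a log2 fold change of at least 1, 32 with no filter on low values, 30 with DESeq2 on the recovered reads, 84 without GFP-negative replicate a, and 23 and 20 without day 0 replicates A and B.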

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

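Tests chosen only after the result was seen were the background and normalization tests of the 488 genes higher in GFP-positive pools, the 3 stem cell tests, the single pool test of the hypoxia genes, and both subtractions of background as alternatives. A total of 50 genes drew attention because they changed in opposite directions from day 0 in the day 35 groups. A difference in the direct comparison of these groups was part of their selection, so the direct values below are no separate test. Of them, 16 rose in GFP-positive and fell in GFP-negative pools, and 34 did the reverse. The direct log2 differences were 5.47 for PMEL, 4.96 for FGF19, 4.55 for the metalloprotease gene ADAMTS16, 3.23 for SHISA2 and 4.73 for CXCL12. They were -3.54 for the endopeptidase-like gene ECEL1, -3.30 for DLL3, -3.20 for the G protein regulator gene RGS16, -2.84 for KLHL13 and -2.57 for the axon guidance receptor gene ROBO3. Subtraction of the largest background ended the calls of the rise from day 0 of PMEL in GFP-positive pools (2.13) and of ECEL1 (1.71), RGS16 (1.46) and ROBO3 (0.89) in GFP-negative pools.

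GFP-positive pools held more genes with any read, 32891 and 31879 against 29798 and 30338, and a higher mean level of reads over 5 of 6 families taken as silent, though both GFP-positive lay above both GFP-negative libraries in only 3 of them (olfactory receptor, keratin-associated protein, and PRAME and SPANX genes), so the 488 genes called higher there were weighed against background. Over the 478 of them with an exon length, the difference between the groups was a median 9.68 times that expected from the family with the largest background rise, and 476 exceeded it. The differences were thus mostly larger than background at that level. These genes had been selected for a difference between the same libraries, so passing that level was partly built in and does not weigh against background. Normalization was the other candidate explanation, and of the 488 genes 90.0% kept the call with TMM factors, 99.0% with quantile normalization and 98.2% in edgeR. The share was lower under some other alternatives, at 70.3% in the 2 groups alone and 61.7% with DESeq2. In limma without trend 42.0% kept the call, and with no filter on low values 29.7%. After subtraction of background at the level of olfactory receptor genes 408 of the 478 kept it, and at the level of the family with the largest rise 245. Of the 233 that lost it there, 188 had a log2 difference at least as large as before and 45 a smaller one, 12 of them under 50% of it. Subtraction can widen a ratio when the lower level comes near the floor, so a larger log2 difference does not clear the 188. A part played by background stays open for all 233. A biological difference between SIX6-positive and SIX6-negative cells remains open as a hypothesis that was not tested apart from the groups themselves.

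Pluripotency genes were higher in GFP-positive than in GFP-negative pools, with 5 of 15 past the threshold, while 2 were lower. Stem cells left in the pools were a candidate explanation, under which LIN28A implied a share of 2.55% of the day 0 level, and 8 of the other 14 list members implied between 1.49% and 3.58%, as left stem cells would give. Most of these 8, POU5F1 among them (77.4 against 59.1), did not pass the threshold between the groups, so their shares may lie within the spread. The remaining 6 of the 14 lay apart, TDGF1 at 0.0639%, DNMT3B at -0.108%, SALL4 at -5.57%, SOX2 at -43.2%, NANOG at 10.2% and LEFTY2 at 396%. A first test, over 5 genes with a day 0 mean of at least 500 and under 1% of it in GFP-negative pools, gave a median rise of 1.38% of the day 0 level and did not decide. A second, chosen because of that outcome, found 13 of 2573 genes with a day 0 mean of at least 200 with an upper counting limit in GFP-positive pools below the LIN28A share, but left out the spread of that share and the number of genes. A stricter test, added after both, with the lowest share over the libraries (1.86%) and a Poisson test with Benjamini-Hochberg adjustment, left 1 gene, TDGF1 at 0.579% of its day 0 level, so stem cells left in the pools stay open. The list still passed after subtraction of the olfactory background (camera, Benjamini-Hochberg adjusted p = 0.00801, median 0.56) and of the largest background (adjusted p = 0.00863, median 0.35), against adjusted p = 0.204 with an estimated correlation and none subtracted. After the latter subtraction the median lies between the bounds set before that test, so that background stays open. LIN28A alone no longer passed (limma, Benjamini-Hochberg adjusted p = 0.0719), although its log2 difference was larger, 3.35 in place of 2.23. Subtraction can widen a ratio when the lower level comes near the floor, so LIN28A does not decide for or against background. Without subtraction the call of the list ended with no filter (camera, Benjamini-Hochberg adjusted p = 0.283) and without GFP-negative replicate c (adjusted p = 0.0537), out of a range from 0.00352 to 0.283 over the alternatives. Background, stem cells, partly differentiated cells and a biological difference between the groups stay open.

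Hypoxia response genes were lower in GFP-positive than in GFP-negative pools, with 10 of 14 past the threshold. The set passed camera with the preset correlation but not with the estimated one of 0.413 (camera, Benjamini-Hochberg adjusted p = 0.244). Normalization was a candidate explanation, and the list median was -0.91 with TMM factors, -0.93 with quantile normalization and -0.86 in edgeR. A single GFP-negative pool was the other, and the median difference to the GFP-positive mean was 0.90 in replicate a and 0.99 in replicate c. Oxygen supply, metabolism or handling of the cells may differ between the groups, and this was not tested directly. Dissociation and stress response genes had 0 of 11 past the threshold (camera, Benjamini-Hochberg adjusted p = 0.352). Mitochondrially encoded genes were lower for 3 of 13 and higher for 0 (camera, Benjamini-Hochberg adjusted p = 0.0256, and adjusted p = 0.599 with an estimated correlation).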

How the results depend on the processing

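Protein-coding genes alone, both background subtractions and the eye field list without SIX6 were chosen only after the results were seen, and the other alternatives before the data were examined. Where the tables do not show a cause below, the cause was not tested. Over the 162 named genes, 9363 comparisons with an alternative stayed on their side of the threshold, 333 lost the call, 82 gained it and 11 reversed. This stability is partly built in, since part of the named genes were chosen for large called differences. Recomputed size factors, which could change nothing, gave 486 of the 9363. With DESeq2, 6 of 122 calls of named genes between the day 35 groups were lost, while 867 of all 1450 calls there were kept. Over the lists 1958 stayed on their side, 67 lost the call, 68 gained it and 1 reversed. A change of direction was counted only where a call was made with or without the alternative. For GFP-positive against GFP-negative pools, the 1450 genes (488 higher, 962 lower) became 494 (156 and 338) with no filter on low values and 630 (236 and 394) in limma without trend. DESeq2 gave 903 in all and 574 lower, a log2 fold change of at least 1 gave 871 and 545, and the higher count was 757 with quantile normalization and 815 in edgeR. With 1 replicate left out the totals ran from 484 to 3295, the higher from 144 to 1253 and the lower from 340 to 2042, lowest without GFP-positive replicate a and highest without GFP-negative replicate a, and of 122 calls of named genes 31 and 2 were lost. A minimum mean of 50, which tests fewer genes, left 13 of 21 list calls, turned the hypothalamus and diencephalon median to 2.02, and gave 5885 changed and 2059 higher genes for GFP-positive and 5219 and 1994 for GFP-negative pools against day 0. Against day 0, GFP-positive pools had 3022 higher among protein-coding genes alone, and quantile normalization turned CCND1 to 0.51 and SOX2 to 0.21 on the log2 scale. Subtraction of the largest background gave 260 higher and 1562 lower genes between the day 35 groups, 2057 and 1810 higher genes for GFP-positive and GFP-negative pools against day 0, and 95 opposite genes. Of the named genes called in these comparisons 10 of 122, 14 of 138 and 20 of 139 lost the call without a change of direction. A further 1, 6 and 0 were counted as changed in direction. The subtraction turned EYA1 between the day 35 groups to 0.00, EBF3 to -0.61, EYA1 to -1.01, POU4F1 to -0.0799, SCUBE2 to -1.07, SYT4 to -0.67 and WNT4 to -0.40 for GFP-positive pools against day 0, and EYA1 to -1.01 and FLRT2 to -3.30 for GFP-negative pools. EBF3, POU4F1, SCUBE2, SYT4 and WNT4 in GFP-positive pools against day 0, and EYA1 between the day 35 groups, no longer passed either. With the replicate block, whose letters share no stated origin and whose pair correlation was -0.0194, 11267 genes changed in place of 10112. GFP-negative pools had 2374 higher genes at a log2 fold change of at least 1, and 2333 (without day 0 replicate A) to 3914 with 1 replicate left out. The 50 genes with opposite changes became 32 with no filter, 30 with DESeq2, 18 at a log2 fold change of at least 1, and 20 (without day 0 replicate B) to 84 (without GFP-negative replicate a) with 1 replicate left out. Depth limits low genes, since 3 reads over a group equal 1.065 normalized counts at day 0, 1.736 in GFP-negative and 1.751 in GFP-positive pools.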

Other observations

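The lists below were fixed before the data were examined, while the comparison of the GFP-negative replicates and its genes were chosen only after their values were seen. For GFP-positive against GFP-negative pools these lists did not pass camera, and each Benjamini-Hochberg adjusted p below is from that test. As adjusted over the list alone, 4 neural crest genes and 3 WNT antagonists were lower, 1 muscle and 1 choroid plexus gene were higher, 1 stress gene was higher and 1 lower, and the other counts stayed as given, retinoic acid genes apart. Neural crest genes had 1 of 9 higher and 3 lower (adjusted p = 0.127), WNT antagonists and receptors 4 of 8 higher and 1 lower (adjusted p = 0.259), hedgehog pathway genes 1 of 8 higher and 1 lower (adjusted p = 0.512), and midbrain and hindbrain genes 1 of 6 higher and 2 lower (adjusted p = 0.623). Stress response, blood vessel and muscle genes had 0 past the threshold of 11, 4 and 5 (adjusted p = 0.352, 0.399 and 0.399). Endoderm genes had 1 of 2 lower (adjusted p = 0.549), photoreceptor genes 1 of 5 lower (adjusted p = 0.625), BMP and TGF-beta ligands 1 of 5 higher (adjusted p = 0.623), and the ventral telencephalon list a single tested member (adjusted p = 0.47). Retinoic acid genes (adjusted p = 0.886) had a median of -0.00 with a mean above 0, and choroid plexus genes, 2 of 5 lower (adjusted p = 0.887), a median of 0.51 with a mean of -0.15. Photoreceptor and midbrain and hindbrain genes had medians of 0.34 and 0.38 with means of -0.13 and -0.07.

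The GFP-negative replicates a and c differed more widely than the other replicate pairs, with a chi-square per gene of 7.89 against 2.20 and 3.20 and a correlation of 0.935. Among single genes, OTP had normalized counts of 5.79 and 78.1 and DLK1 of 97.0 and 822, in that order.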
